A study of Drosophila melanogaster with 16 samples.

How the data were processed

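Gene expression was measured by RNA sequencing of dissected midguts, the main digestive and absorptive part of the fly intestine. Flies were virgin males and females of a control genotype carrying the enterocyte driver mex1-GAL4 and of a genotype in which that driver was combined with a Myc RNAi line, so the design crosses sex with genotype. Each of the 4 groups holds 4 libraries, and each library was made from 30 pooled guts; the series describes 3-4 independent samples for each sex and genotype. All 16 labelled libraries were used. Libraries were assigned to groups from their titles.

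The values are whole-number read counts per gene, deposited by the authors as 1 table with a column for each of the 16 libraries and no normalization. Per the labels' protocols, RNA was isolated with the RNeasy kit, poly(A) RNA was selected, and strand-specific libraries were made with the NEBNext Ultra II Directional kit. The dm6 genome build, TopHat2 2.0.11 and featureCounts are named for the counts per the submitters' processing notes. The gene annotation, the strand setting of the counting, the rule for reads that map to several places and the featureCounts version are not given in the sources used here. Values of overlapping or antisense genes, and of near-identical copies such as the Hsp70 genes, the tandem LMan genes or the Amy pair, are therefore uncertain, because reads could have been shared, dropped or assigned to a neighbour. The 16680 genes of the table are given as symbols. Of these, 12504 matched a current symbol and 4006 a synonym in the reference gene table, and 170 matched neither; 1917 had a count in no library. Printed names are current symbols. Coordinates are 1-based and come from the Ensembl annotation of the BDGP6 assembly, the same sequence as dm6.

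Total counts ranged from 16630050 to 53586401 per library. Before averaging, all 24 pairs of replicates were compared. Their counts differed by more than sampling noise (chi-square per degree of freedom 25.8 to 326), with Pearson correlations of log2 values between 0.939 and 0.986, so no library was treated as a second copy of another.

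Genes were filtered with edgeR's filterByExpr by group, which left 9314 genes for testing. Libraries were scaled with TMM factors, and the normalised counts (CPM) below use them, as mean ± SD over 4 libraries. The edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) was fitted to all 16 libraries with 1 mean per group. It gave 5 comparisons: the libraries labelled Myc RNAi against controls within females and within males, females against males among controls and among the libraries labelled Myc RNAi, and the interaction, which is the female effect minus the male effect. A gene counted as changed when its p, adjusted over all tested genes by the Benjamini-Hochberg method, was below 0.05; "edgeR adjusted p" stands for that value. Standard errors (SE) of log2 fold changes were obtained from the estimate and the F statistic. The p-values measure the spread between pools of guts.

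Before the data were examined, 37 gene lists were written down for pathways and for cell types that a gut dissection can hold, together with the tests, the alternatives and the rule for naming genes. Of their entries, 9 found no match in the table. Camera in limma 3.58.1 compared each list with all other genes at a preset inter-gene correlation of 0.01, adjusted over the 35 lists with at least 3 tested members. Camera with an estimated correlation and fry were run beside it. Numbers of changed list members are given from the adjustment over all genes and, as "adjusted over the list alone", from an adjustment within the list. The estimated correlation ended most list calls, and its adjusted p stands beside each such result. The ovary list had 2 tested members and the list for testis and accessory gland had 1, so neither was tested; the reads of the latter are described gene by gene.

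The naming rule took, per comparison, the 10 genes with the largest rise and the 10 with the largest fall (5 and 5 for the interaction). Genes had to be changed, to reach a mean of 5 CPM in the higher group and, except for the interaction, to show no overlap between the libraries compared. Genes known only by a CG or CR number were set aside, and up to 2 per direction could be named. From each list discussed, up to 4 changed members with the lowest p could be named, and sex-determination genes were fixed as a check of the labels. Other genes named below were chosen after their values were seen; these are list members that moved against their list, and the genes of the last part. For a group without reads, a fold is a lower bound against a floor of 3 reads over the group, which covers counting error only.

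The sex difference kept in the libraries labelled Myc RNAi was measured on held-out libraries. Sex-biased genes were called between 2 female and 2 male control libraries, and their median log2 sex difference was taken in the other control libraries and in the libraries labelled Myc RNAi. All 36 choices of libraries were used. The design fixed the mean and range of these medians. The share kept is the ratio of the means, and other ways of averaging it were added after seeing the data.

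Alternatives were other scalings, other filters, other thresholds, DESeq2 1.42.0, limma voom, a robust prior, fits to the 8 libraries of a comparison and leaving out each library in turn. No GC correction was made. The steps were tested on simulated data, drawn once per comparison around 1 mean per gene over all 16 libraries, with the real library sizes and spread. In 1 group 200 genes were changed, as many up as down, and nothing else differed between the groups. The shares below therefore do not test the difference in composition between the genotypes of the real libraries. Among genes changed 2-fold, the share recovered was 56.1% for the female comparison (9237 genes tested), 49.3% for the male comparison (9242), 70.1% for the sexes in controls (9243), 64.2% for the sexes labelled Myc RNAi (9238) and 26.9% for the interaction (9240). False calls made up 3.7%, 3.8%, 4.7%, 3.5% and 7.7% of all calls in the same order. For genes changed 1.5-fold the interaction recovered 6% and for 4-fold 75.8%. A simulated kept share of 33.3% was estimated as 34.6%. There all sex-biased genes had the same fold difference, so the wide range among the real choices of libraries was not reproduced.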

Results

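RNA of dissected midguts was sequenced from virgin female and male flies of a control genotype and of a genotype labelled as Myc RNAi driven by mex1-GAL4, with 4 libraries per group. The title of the series names Myc, the regions of the gut and sex-biased zonation as its subject. Total counts were 20445688, 31752151, 26911264 and 18986654 in the female controls and 27922532, 34141792, 34586333 and 50720292 in the male controls. In the libraries labelled Myc RNAi they were 24946535, 16630050, 53586401 and 26786569 in females and 22870888, 18239086, 25064185 and 46358475 in males. The 50 most abundant genes held 26.9% to 38.6% of the counts in control libraries and 21.8% to 24.2% in the libraries labelled Myc RNAi. TMM factors accordingly differed between genotypes, from 0.691 to 1.01 in controls and from 1.12 to 1.23 in the others.

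Myc, the growth-promoting transcription factor targeted by the RNAi line (listed as dm; FBgn0262656, chromosome X, 3373159 to 3391697), was examined first. Its level was 126.5, 84.6, 60.5 and 84.9 CPM in the female controls and 83.6, 51.7, 56.9 and 43.7 CPM in the females labelled Myc RNAi, a log2 fold change of −0.59 (SE 0.26, edgeR adjusted p = 0.0892). In males it was 22.7, 19.8, 25.4 and 34.0 CPM in controls and 30.6, 33.3, 35.7 and 60.2 CPM in the libraries labelled Myc RNAi, a log2 fold change of 0.65 (SE 0.26, edgeR adjusted p = 0.0619). Neither difference passed the test, and in males the transcript went against the label. The groups are called "labelled Myc RNAi" for that reason.

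The Myc result depended on settings. The lower level in females passed without replicate 3 (Myc log2 fold change −0.74, edgeR adjusted p = 0.0411) or 9 (−0.81, edgeR adjusted p = 0.0288), and in the fit without male replicate 16 (edgeR adjusted p = 0.0486). It moved to −0.38 without replicate 1 (edgeR adjusted p = 0.305) and to −0.17 with total-count scaling (0.657). The higher level of Myc in males passed without replicate 8 (0.82, edgeR adjusted p = 0.0328) or 13 (0.75, edgeR adjusted p = 0.0463), with total-count scaling (1.09, edgeR adjusted p = 0.00606) and with DESeq2 (0.62, adjusted p = 0.0491). Without replicate 16 it moved to 0.38 (edgeR adjusted p = 0.248). The white gene w (chromosome X, 2790599 to 2796466), whose marked copies are carried by many transgenes, separated the genotypes completely. It rose from 14.4 to 340 CPM in females (log2 fold change 4.56, SE 0.19, edgeR adjusted p = 1.89e-10) and from 23.6 to 460 CPM in males (4.29, SE 0.19, edgeR adjusted p = 3.4e-10). The dosage-compensation RNA roX1 followed the sex labels in all libraries, at 0.865 ± 0.650 and 1.13 ± 0.636 CPM in the female groups against 720 ± 109 and 719 ± 43.2 CPM in the male groups.

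**Figure D1:**
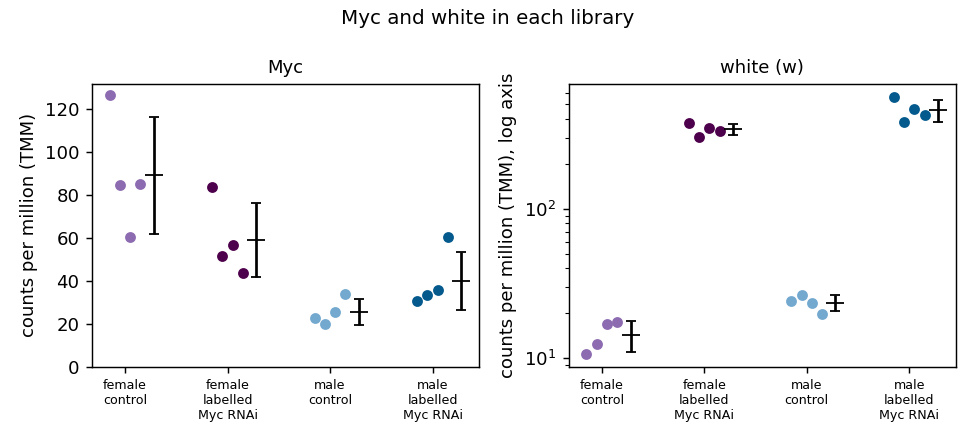
Normalised counts (CPM) of Myc (left, linear axis) and of the white gene (right, log axis) in each library, with the mean and SD of 4 libraries per group. Myc averaged 89.1 and 59.0 CPM in control females and females labelled Myc RNAi and 25.5 and 39.9 CPM in the corresponding males, while white separated the genotypes in both sexes.

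In females labelled Myc RNAi, transcripts for digestive enzymes and for the ribosome were lower than in controls, and cell cycle genes, markers of progenitor cells and some markers of enterocytes were higher. Among cytosolic ribosomal proteins, 79 of 83 measured members fell (81 adjusted over the list alone), with a median log2 change of −1.33; RpL5 dropped from 4090 ± 1150 to 1200 ± 132 CPM (log2 fold change −1.77, SE 0.20, n = 4 per group). Among digestive serine proteases 23 of 26 fell (also 23 adjusted over the list alone), such as Jon99Ci, at 5960 ± 1270 CPM in controls and 909 ± 170 CPM in the other group (−2.71, SE 0.23). Among them were zetaTry (−2.84), Jon99Cii (−2.68) and Jon99Ciii (−2.88). The trypsin gene etaTry went the other way (0.45, edgeR adjusted p = 0.0116, and 0.07 without replicate 4). Of 14 starch- and sugar-digesting enzymes 11 fell (12 adjusted over the list alone), including the amylase Amy-p (−2.14, SE 0.24) and the maltase Mal-A7 (−1.13, SE 0.13). By contrast 26 of 31 cell cycle genes rose (29 adjusted over the list alone), with a median of 1.44, among them aurB (1.77), RnrL (1.91), Mcm7 (2.13) and Cdk1 (2.08). All 14 markers of intestinal stem cells and enteroblasts rose, as they did adjusted over the list alone, including Sox21a (1.97, SE 0.38), Sox100B (1.93) and Delta (1.37); 9 rose without replicate 2. Of 11 enterocyte genes 6 rose (7 adjusted over the list alone) and none fell, led by the smooth septate junction genes Ssk (1.20), Tsp2A (1.16) and mesh, at 1490 ± 281 and 3840 ± 396 CPM (1.37, SE 0.20).

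The largest single changes in females included ninaD, a scavenger receptor for carotenoid uptake (chromosome 2L, 18081628 to 18083608), which dropped from 334 ± 170 to 7.89 ± 7.13 CPM (log2 fold change −5.38, SE 0.78, edgeR adjusted p = 5.37e-05). The amylase-related gene Amyrel (−4.53, SE 0.39), the lipase genes Lip3 (−4.27) and mag (−3.59), PGRP-SC1a (−3.92), Jon74E (−3.87), Ser8 (−3.73), smp-30 (−3.61), Jon25Bii (−3.54) and Ugt37B1 (−3.53) also fell, as did CG4830 (−5.53) and CG31741 (−5.18). Beside w, large rises were found in Hsp70Bb (10.23, SE 0.48), one of several near-identical heat shock genes with 5 reads over all female controls, HmgD (4.02, SE 0.26), eys (3.76), Cyp12e1 (3.60, SE 0.13), the lysozyme gene LysX (3.43), the chitinase gene Cht12 (3.36), Hsp23 (3.35), Lip4 (3.16), Wsck (2.87), CG31955 (4.56) and CG13318 (4.22). The near-identical copies of Hsp70Bb did not match its rise. Hsp70Ba had 16 reads in female controls and 123 in females labelled Myc RNAi, Hsp70Bbb 12 and 18, and Hsp70Bc 13 and 11. Whether the Hsp70Bb reads came from the gene itself was not tested. In total 3362 of 9314 genes changed, 1727 higher and 1635 lower, and 749 and 681 of these by more than 2-fold. With libraries scaled to total counts alone, the median of all genes shifted to 0.43 in females and 0.52 in males (0 and 0.05 with TMM), and the female split became 3488 higher and 672 lower.

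Camera called 11 of the 35 lists in females, and none of these calls held with an estimated correlation. For the lists described above, camera adjusted p was 6.15e-26 for ribosomal proteins (adjusted p = 0.372 with an estimated correlation), 1.35e-16 for serine proteases (0.22 in the same form), 7.39e-09 for starch and sugar digestion (0.22), 1.25e-11 for cell cycle (0.22), 2.61e-05 for stem cells and enteroblasts (0.372) and 0.000948 for enterocytes (0.22). Ribosome biogenesis genes were also lower: 29 of 45 fell (31 adjusted over the list alone), with Non1 (−1.80), the Pescadillo gene CG4364 (−1.51), nclb (−1.21) and LTV1 (−1.13) (camera adjusted p = 6.07e-09, adjusted p = 0.22 with an estimated correlation). Of 45 translation factors 22 fell (23 adjusted over the list alone), such as eIF2A (−1.12), while eIF4EHP (1.51), which represses translation, and eIF4G2 (1.27) rose (camera adjusted p = 0.00145, adjusted p = 0.22 with an estimated correlation). Total-count scaling brought the median of the translation factors from −0.40 to −0.006. Among 10 alpha-mannosidases and lysozymes 7 fell (7 adjusted over the list alone) and LysX rose (camera adjusted p = 0.0031, adjusted p = 0.226 with an estimated correlation). Fatty acid oxidation fell in 8 of 14 members (9 adjusted over the list alone), among them Acox57D-p (−1.34), although total-count scaling turned its median from −0.40 to 0.05 (camera adjusted p = 0.00935, adjusted p = 0.641 with an estimated correlation). Of 20 lipid genes 7 fell (8 adjusted over the list alone), and Lip4, the fatty acid synthase FASN1 (1.09) and the lipase Hsl (0.42) rose (camera adjusted p = 0.0364, adjusted p = 0.372 with an estimated correlation). That last call ended without replicate 3 or 9 (camera adjusted p up to 0.083) and with a filter of 1 CPM (0.0529). The call of FASN1 ended without replicate 2 (edgeR adjusted p = 0.0525) and that of Hsl without 1, 2, 4, 10, 11 or 12 (up to 0.104).

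**Figure D2:**
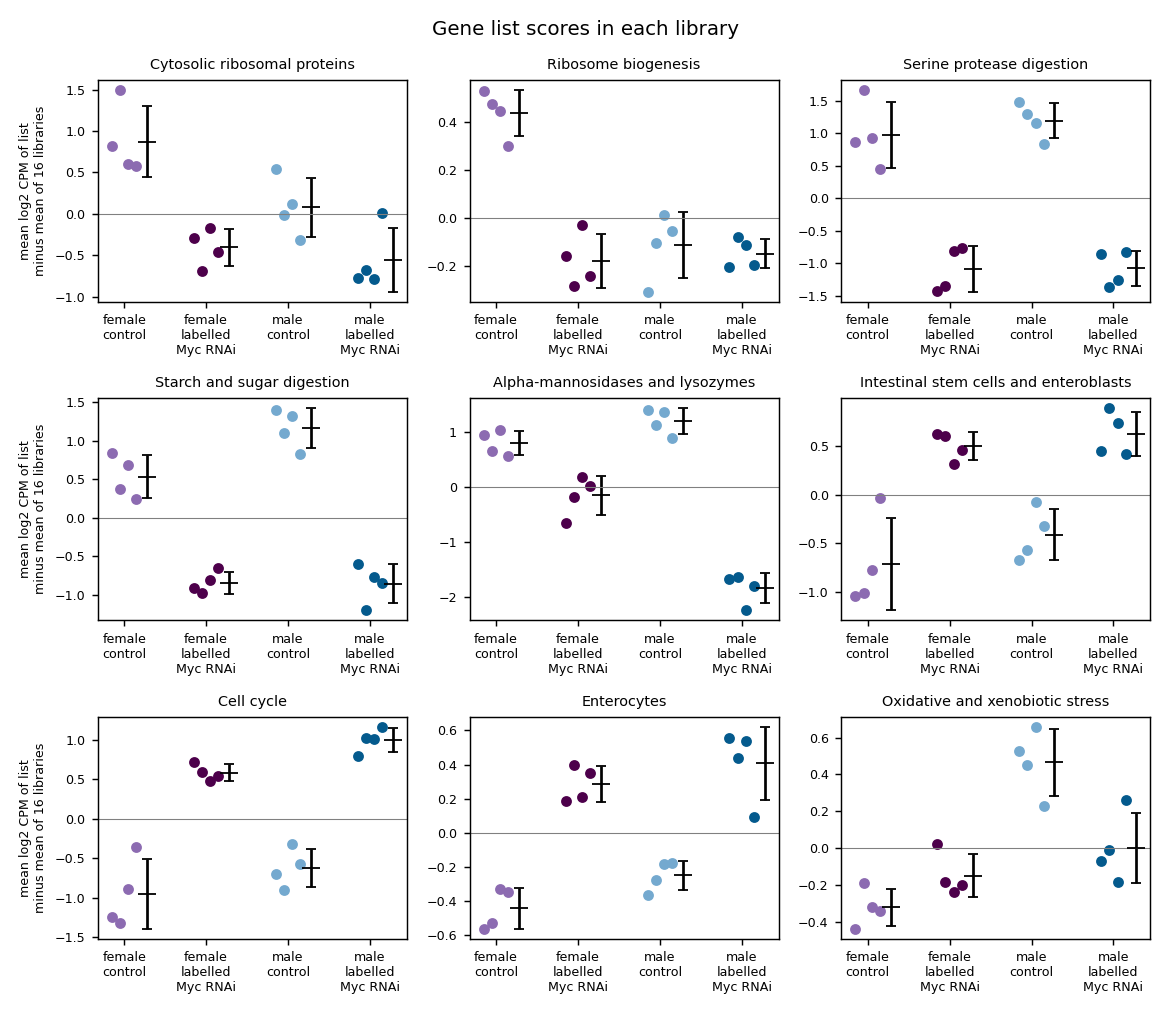
Scores of 9 gene lists in each library, as the mean log2 CPM of the list's tested members minus its mean over the 16 libraries (vertical axis, log2 units), with the mean and SD of 4 libraries per group. The ribosomal protein score of male Myc RNAi replicate 16 was 0.02 while the other 3 libraries of its group lay between −0.79 and −0.68.

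In males labelled Myc RNAi, starch-digesting enzymes, serine proteases and alpha-mannosidases fell further than any other list, and cell cycle genes and some enterocyte markers were higher. Of 14 starch- and sugar-digesting enzymes 13 fell (14 adjusted over the list alone), with a median of −2.11; Mal-A7 went from 12400 ± 1200 to 2860 ± 225 CPM (log2 fold change −2.12, SE 0.14, n = 4 per group). Mal-A4 went from 6330 ± 996 to 792 ± 184 CPM, and Mal-A3 (−2.57) and Mal-A8 (−2.10) fell as well. Of 26 serine proteases 23 fell (25 adjusted over the list alone), including Jon99Ci, at 10200 ± 1400 and 1540 ± 418 CPM (−2.72, SE 0.23), zetaTry (−3.25) and Jon25Biii (−4.05), while etaTry rose (0.71). In the list of alpha-mannosidases and lysozymes 8 of 10 fell (8 adjusted over the list alone), with a median of −3.90; LManIII went from 2050 ± 541 to 38.3 ± 8.58 CPM (−5.74, SE 0.36) and LManVI from 8840 ± 2310 to 457 ± 22.8 CPM, and LysX rose (4.15, SE 0.41). Of 31 cell cycle genes 29 rose (29 adjusted over the list alone), such as polo (2.52), Mcm7 (2.19) and aurB (1.45), and of 14 stem cell and enteroblast markers 9 rose (11 adjusted over the list alone), including Sox21a (2.05). Of 11 enterocyte genes 7 rose (7 adjusted over the list alone), including Tsp2A (1.53) and mesh, at 1780 ± 232 and 5040 ± 1320 CPM. The transcription factor gene GATAe of the same list fell (−0.61). The call of GATAe ended without replicate 6, 7, 8, 13 or 16 (edgeR adjusted p up to 0.105; log2 fold change −0.45 without 16).

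Ribosomal proteins were lower in these males by a median of −0.68, with 43 of 83 members fallen (56 adjusted over the list alone); RpL5 had 2260 ± 508 CPM in controls and 1010 ± 164 CPM in the libraries labelled Myc RNAi (log2 fold change −1.15, SE 0.20). RpS5b, a paralogue most abundant in germ cells, had a log2 fold change of 2.14 (edgeR adjusted p = 0.0329). It was 0.13 without replicate 16 (edgeR adjusted p = 0.846), and the call also ended without 5, 6, 7 or 8. Replicate 16 of this group stood apart: it held 23981 reads from 9 testis germline genes such as Mst87F and dj, against 12 to 34 in the other 3 libraries of the group. Without that library 77 ribosomal protein genes fell, with a median of −0.89, while 24 fell without replicate 5, 21 without 13, 27 without 14 and 21 without 15. Ribosome biogenesis genes had a median of −0.02 in males and were not called (camera adjusted p = 0.693); 7 fell, and the small nucleolar ribonucleoprotein genes Fib (0.88), nop5 (0.69), Nop60B (0.64) and Nop56 (0.44) rose.

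The largest falls in males were in LManIV (log2 fold change −7.65, SE 0.59, edgeR adjusted p = 7.46e-08), ninaD (−7.64, SE 0.87), LManIII, Lip3 (−5.59), smp-30 (−5.40), the protease gene Bace (−5.07), Ser8 (−5.04), the zinc transporter gene Zip42C.1 (−4.92), Amyrel (−4.83), Eo (−4.76), CG31741 (−7.51) and CG31091 (−7.32). Hsp70Bb (10.88, SE 0.49), again not matched by its near-identical copies, eys (4.30), w and LysX were among the largest rises. The others were djl (6.75), Mst84B (6.29), tomboy40 (5.77), ms(3)76Cc (4.33), TTLL4B (4.25), Pen (4.13), CG7634 (5.19) and CG15128 (5.17), whose values without replicate 16 were 3.54, 2.64, 2.14, 2.47, 1.46, 2.31, 1.81 and 1.42. For djl that value rests on few reads, 48 over replicates 13 to 15 and 6 over the controls of both sexes. Such traces were not limited to males, since females labelled Myc RNAi held 38 djl and 23 Mst84B reads against 0 in female controls. With limma voom, Mst84B, tomboy40, TTLL4B, CG7634 and CG15128 were not called (adjusted p between 0.0589 and 0.0878). In all 3671 genes changed, 2025 higher and 1646 lower, and 3707 changed without replicate 16. Total-count scaling gave 4460 higher and 776 lower.

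Camera called 12 of the 35 lists in males. The fall of alpha-mannosidases and lysozymes held with an estimated correlation (camera adjusted p = 4.47e-12 preset, 0.0113 estimated). For the other lists above, camera adjusted p was 1.44e-15 for starch and sugar digestion (adjusted p = 0.0804 with an estimated correlation), 2.58e-15 for serine proteases (0.315 in the same form), 1.32e-10 for cell cycle (0.315), 3.31e-06 for ribosomal proteins (0.737), 0.00305 for stem cells and enteroblasts (0.731) and 0.00648 for enterocytes (0.363). Fatty acid oxidation fell in 9 of 14 members (9 adjusted over the list alone; camera adjusted p = 0.00305, adjusted p = 0.731 with an estimated correlation). Lipid genes fell in 11 of 20 (12 adjusted over the list alone), among them ATPCL (−1.76), while Lip4 (2.78) and Hsl (0.46) rose (camera adjusted p = 0.00398, adjusted p = 0.363 with an estimated correlation). In the list of oxidative and xenobiotic stress genes 16 of 34 fell (16 adjusted over the list alone), such as the catalase gene Cat (−2.06) and Prx2 (−1.68), and 5 glutathione transferases rose: GstD5 (0.70), GstD6 (1.66), GstD8 (2.32), GstD9 (1.59) and GstE11 (0.61) (camera adjusted p = 0.00523, adjusted p = 0.731 with an estimated correlation). Glycolysis fell in 6 of 14 members (6 adjusted over the list alone), led by Pgi (−2.26), although total-count scaling turned its median from −0.37 to 0.10 (camera adjusted p = 0.0285, adjusted p = 0.731 with an estimated correlation). Among 9 genes of the copper-cell and iron-cell region 5 fell (5 adjusted over the list alone), such as Fer1HCH (−1.21) and MtnD (−1.70), with the same values of both tests. The calls of Hsl and GstE11 ended without replicate 13 (edgeR adjusted p = 0.062) and without 6, 8 or 16 (up to 0.0649). The glycolysis call ended without replicate 5 or 14 (camera adjusted p up to 0.0592) and in a fit to the 8 male libraries (0.0514), and the copper and iron call without replicate 16 (0.055).

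The effects in the sexes were then set side by side across genes. Of the genes called higher, 1420 were shared between females and males (375.5 from independent lists of the same sizes), and of those called lower 1157 (288.9). Only 6 genes were called in opposite directions. Across the 9314 tested genes the log2 fold changes had a Pearson correlation of 0.714 and a Spearman correlation of 0.738, and 78.7% had the same sign; genes are not independent replicates, and the comparisons share no library. Without female control replicate 1 the Pearson correlation was 0.545. Genes of this shared kind included ninaD, Amyrel, Lip3, Ser8 and smp-30, named among the 10 largest falls in each sex.

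Whether the libraries labelled Myc RNAi differed from controls in another way in each sex was tested by the interaction. Differences were found in alpha-mannosidases, lysosomal-type enzymes that trim sugar chains and whose tandem paralogues on chromosome 2L (LManIII to LManVI, 8765273 to 8781252) could share reads. LManVI dropped from 4180 ± 1010 to 1320 ± 315 CPM in females and from 8840 ± 2310 to 457 ± 22.8 CPM in males (n = 4 per group), a female-minus-male difference of 2.61 (SE 0.31, edgeR adjusted p = 0.00106). LManIV (4.38, SE 0.66), LManIII (3.16, SE 0.42), LManV (2.67, SE 0.31) and LManI (1.66, SE 0.21) also fell more in males, and so did Bace, from 4620 ± 1830 to 138 ± 66.3 CPM in males against 15500 ± 7170 to 5050 ± 239 CPM in females (3.45, SE 0.51, edgeR adjusted p = 0.00377). Ribosome biogenesis genes went the other way. Nop56, a core protein of small nucleolar ribonucleoproteins (chromosome 3R, 22419095 to 22421068), fell in females from 56.4 ± 6.98 to 37.0 ± 2.61 CPM and rose in males from 31.9 ± 2.64 to 43.3 ± 2.27 CPM (difference −1.05, SE 0.15, edgeR adjusted p = 0.00318).

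Within the fixed lists, 6 of 10 alpha-mannosidases and lysozymes differed in that direction (8 adjusted over the list alone; camera adjusted p = 1.1e-27 preset, 0.000274 estimated). Of 45 ribosome biogenesis genes 6 passed with a negative female-minus-male difference (20 adjusted over the list alone, camera adjusted p = 2.18e-22 preset, 0.0168 estimated). Among them were nop5 (−1.01), Nop60B (−0.84), bys (−0.77) and Fib (−1.04). Gar1 (−1.43), which is not on that list, differed in the same direction. In Fib the female effect was −0.16 (edgeR adjusted p = 0.504) and the male one 0.88. Starch and sugar enzymes differed in 4 of 14 members (8 adjusted over the list alone), among them Mal-A4 (1.63), Mal-A3 (1.21), Mal-A7 (0.98) and Mal-A8 (0.98), having fallen more in males (camera adjusted p = 6.92e-10, adjusted p = 0.134 with an estimated correlation). No member of the ribosomal protein, translation factor, mitochondrial ribosomal protein, stress or antimicrobial lists passed over all genes, although camera called these lists. Their adjusted p values with an estimated correlation were 0.494, 0.134, 0.671, 0.134 and 0.671. The same holds for the Myc network list (0.146), while Pgi of the glycolysis list (1.42; list 0.181), MtnD of the copper and iron list (2.01; list 0.181) and crq of the hemocyte list (0.80; list 0.519) passed. Adjusted over the list alone, 16 stress genes, 3 glycolysis genes, 4 copper and iron genes, 2 Myc network genes and 1 hemocyte gene differed. The hemocyte call ended without replicate 2 or 16 (camera adjusted p up to 0.0883), and the antimicrobial call without replicate 1, 2, 4, 5, 6, 7, 11, 12, 14 or 15 (up to 0.423) and with no filter (0.0969).

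Most of these members depended on single libraries. Of the ribosome biogenesis genes 1 was called without replicate 6, 12 or 15, 2 without 1, 5, 9 or 10, 3 without 2, 3, 8, 13 or 14 and 10 without 16. Of the starch and sugar enzymes 1 was called without replicate 6, 2 without 12 and none without 15. Of the stress genes 1 was called without 2, 4, 5, 14 or 16 and 2 without 3. Calls that ended when 1 library was left out were those of crq (all but 5 and 7; edgeR adjusted p up to 0.112, and 0.0537 without 16) and bys (all but 4, 11 and 16; 0.097). The same holds for Pgi (1, 2, 4, 6, 9, 12, 13, 14 or 15; 0.0751) and MtnD (4, 6, 7, 9, 11, 12, 13, 14 or 15; 0.0845). The others were Nop60B (1, 5, 6, 9, 10, 11, 12, 13 or 15; 0.0857), Mal-A8 (1, 4, 6, 7, 9, 11, 12 or 15; 0.0716), nop5 (6, 12 or 15; 0.0544), Mal-A3 (6, 12 or 15; 0.0577), Mal-A4 (6 or 15; 0.0544) and Mal-A7 (15; 0.0577).

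In total 100 genes passed the interaction test, 81 with a positive female-minus-male difference. Of the 100, 70 were lower in both sexes and more so in males. For 23 the signs were opposite. Further named genes were gol, which rose in both sexes and more in males (−1.49, SE 0.26), Zip42C.2 (−1.61, SE 0.35), CG6296 (−3.36, SE 0.49), which fell in females from 121 ± 33.6 to 11.4 ± 5.48 CPM and had 49.0 ± 18.8 and 48.1 ± 15.3 CPM in males, CG31454 (−1.57), CG34316 (3.87, SE 0.83) and CG31091 (2.95, SE 0.68). Myc itself had a difference of −1.24 (SE 0.37, edgeR adjusted p = 0.155), which DESeq2 called (adjusted p = 0.0438). The count depended on single libraries: it was 62 without replicate 1, 40 without 6, 52 without 9, 61 without 11, 46 without 12, 59 without 13 and 36 without 15. Without replicate 4 there were 75, of which 48 had a positive female-minus-male difference. Calls of named genes that ended when 1 library was left out were those of Gar1 (without 1, 6, 9, 10, 12, 13 or 15; edgeR adjusted p up to 0.0716), Zip42C.2 (2, 3, 5, 6, 8, 9, 10, 12, 13 or 15; 0.081), CG34316 (all but 1, 5, 8, 11 and 16; 0.0819), CG31091 (all but 5, 9 and 16; 0.114) and Fib (all but 4, 7 and 11; 0.114). Limma voom did not call CG34316 (adjusted p = 0.238) or CG31091 (0.106), and total-count scaling ended the calls of CG34316, CG31091 and Gar1 (edgeR adjusted p = 0.0542, 0.0608 and 0.0894) and gave 57 genes.

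**Figure D3:**
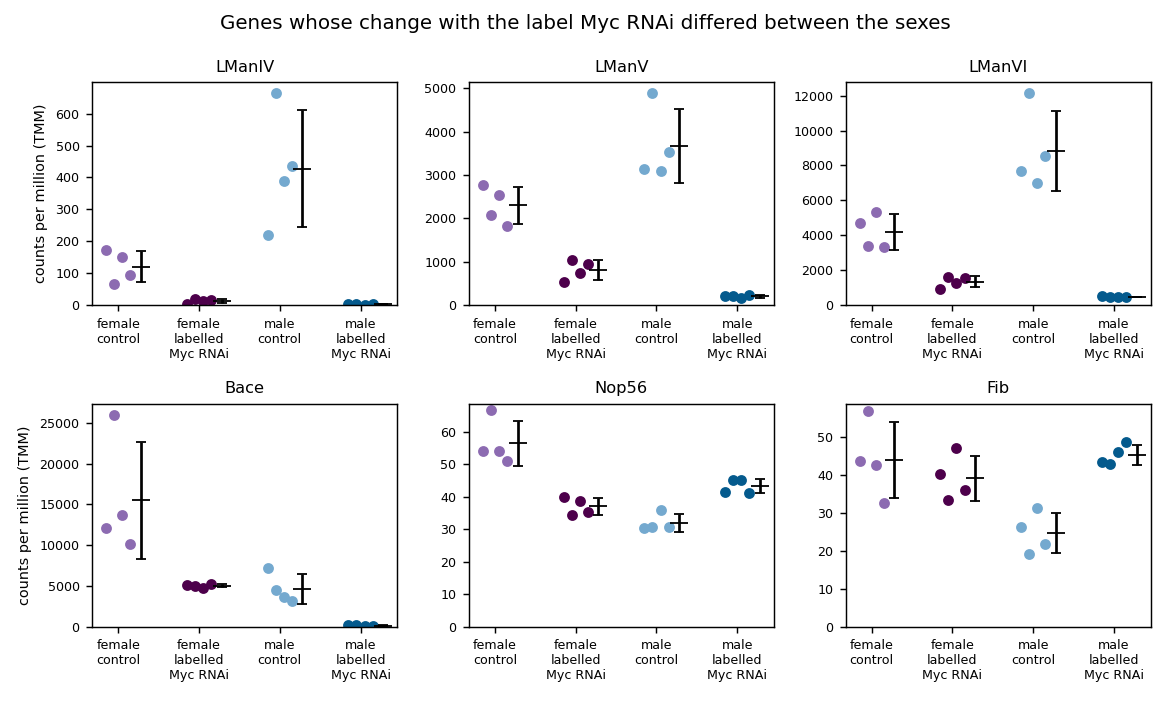
Normalised counts (CPM, linear axes) of 6 genes whose difference between control and labelled libraries was not the same in the sexes, in each library, with the mean and SD of 4 libraries per group. The alpha-mannosidase genes and Bace were lowest in males labelled Myc RNAi, with LManVI at 457 CPM there, while Nop56 and Fib were higher in those males than in control males.

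Among controls, yolk protein genes were higher in females and dosage-compensation RNAs in males. The yolk protein gene Yp2 had 49.0 ± 26.0 CPM in females and 0.429 ± 0.356 CPM in males (log2 difference, female minus male, 7.04, SE 0.68, edgeR adjusted p = 1.78e-05), and Yp1 (6.52) and Yp3 (3.19) were also higher in females. No roX2 read was found in female controls against 2210 in male controls, so the male level was at least 490-fold higher. Among the regulators of sex, msl-2 (−1.71) and dsx (−1.27) were higher in males and tra (0.76) in females, while Sxl differed by 0.40 (edgeR adjusted p = 0.102). Myc was higher in females, at 89.1 ± 27.4 against 25.5 ± 6.10 CPM (1.80, SE 0.27, edgeR adjusted p = 0.000695). Ribosome biogenesis genes were higher in females for 22 of 45 members (31 adjusted over the list alone), such as Nop56 (0.82, SE 0.10), nop5 (0.92) and CG4364 (0.99), and ribosomal proteins for 49 of 83 (78 adjusted over the list alone), such as RpL8 (0.98) and RpS2 (1.06). These counts rested on single libraries: ribosomal proteins numbered 23 without replicate 1, 5 without 2 or 6, 13 without 7 and 6 without 8. Male controls had higher levels of the stress enzymes GstD5 (−2.03), GstD3 (−2.23) and GstD9 (−1.27), of the maltases Mal-A7 (−0.90) and Mal-A5 (−1.32), of the immune genes DptA (−3.39), Def (−2.53) and PGRP-SD (−2.36), and of the enteroendocrine genes AstA (−1.22) and Cadps (−1.78).

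Other genes higher in control females were the amino acid transporter gene slif, at 177 ± 87.9 against 39.3 ± 8.55 CPM (2.17), apolpp (1.98), FucTC (1.82), sug (1.80), Bace (1.75), Oatp74D (1.74), CG12057 (7.94) and CG4563 (3.38). Higher in control males were roX1 (−9.73), fs(1)Yb (−6.15), sev (−3.67), tyn (−3.40), DptB (−3.26), Oat (−2.94), CG7017 (−4.03) and CG6026, which had 1 read in female controls. In all 959 genes differed, 468 higher in females and 491 higher in males; total-count scaling gave 497 and 297. The count was 603 without replicate 1, 574 without replicate 6 and 1292 without replicate 16; a fit to the 8 control libraries alone gave 538. Without replicate 2, 651 genes split into 266 higher in females and 385 higher in males, without 8 into 273 and 372, and without 4 into 588 and 404. Calls ended for apolpp (without replicate 2, 3, 5, 6, 7 or 8; edgeR adjusted p up to 0.123), sug (2, 6 or 7; 0.0654), DptB (1 or 2; 0.0589) and tra (1, 2, 4, 5, 6, 7 or 8; 0.122).

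Camera called 16 of the 35 lists between control females and males, and none held with an estimated correlation. Ribosomal proteins were called higher in females (camera adjusted p = 1.32e-29, adjusted p = 0.283 with an estimated correlation), as was ribosome biogenesis (camera adjusted p = 1.46e-18, adjusted p = 0.0752 with an estimated correlation). Translation factors were higher in females for 15 of 45 members, 19 adjusted over the list alone (camera adjusted p = 5.12e-07, adjusted p = 0.0929 with an estimated correlation); 9 passed without replicate 1, 7 without 2 or 6 and 6 without 8. Mitochondrial ribosomal proteins were higher for 10 of 72, 18 adjusted over the list alone (camera adjusted p = 8.13e-10, adjusted p = 0.515 with an estimated correlation). Without replicate 1 they numbered 6, without 2 or 8 they numbered 3, without 6 they numbered 4, and without 4 or 16 they numbered 16. Aminoacyl-tRNA synthetases were higher for 3 of 20, also 3 adjusted over the list alone (camera adjusted p = 0.0162, adjusted p = 0.515 with an estimated correlation), and for 1 without replicate 1, 2, 5, 6 or 7. In the Myc network list Myc and bigmax (0.97) were higher, and 3 members adjusted over the list alone (camera adjusted p = 0.00641, adjusted p = 0.128 with an estimated correlation). Oxidative phosphorylation was called higher in females (camera adjusted p = 1.89e-05, adjusted p = 0.674 with an estimated correlation). Its 1 changed member of 65, Cyt-c-p, was higher in males (−0.58) and did not pass adjusted over the list alone; its call ended without replicate 1, 4, 6 or 7 (edgeR adjusted p up to 0.113). That list call ended without replicate 2 (camera adjusted p = 0.0803).

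Stress genes were higher in control males for 16 of 34 members, 20 adjusted over the list alone (camera adjusted p = 1.45e-13, adjusted p = 0.104 with an estimated correlation). Starch and sugar enzymes were higher in males for 8 of 14, 10 adjusted over the list alone (camera adjusted p = 1.37e-09, adjusted p = 0.128 with an estimated correlation). Of 24 antimicrobial and recognition genes 8 were higher in males and 1 in females, 16 and 1 adjusted over the list alone (camera adjusted p = 4.46e-08, adjusted p = 0.208 with an estimated correlation). Without replicate 1 or 5 there were 5 higher in males, without 2 there were 4, and the 1 higher in females did not pass without 3, 6 or 8. Enteroendocrine genes were higher in males for 4 of 21, 6 adjusted over the list alone (camera adjusted p = 0.000191, adjusted p = 0.228 with an estimated correlation). Alpha-mannosidases and lysozymes were higher in males for 3 of 10, and adjusted over the list alone for 7 with 1 the other way (camera adjusted p = 0.00339, adjusted p = 0.212 with an estimated correlation). The sex-determination list was called higher in males although its median was 0.15, with 4 members in each direction and 5 in each adjusted over the list alone (camera adjusted p = 0.0216, adjusted p = 0.127 with an estimated correlation). That call ended with total-count scaling (camera adjusted p = 0.061) and with no filter on low counts (0.46).

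Of the control lists called higher in males, 3 depended on single libraries. Cell cycle genes differed in RnrS (−0.91) and Mcm3 (−0.83), also 2 adjusted over the list alone (camera adjusted p = 0.0421, adjusted p = 0.674 with an estimated correlation), and the call ended without replicate 1, 2, 5, 7 or 16 (up to 0.231), with the 8 control libraries alone (0.0806) and with the 50 top genes out of scaling (0.0518). The call of Mcm3 ended without 1 or 2 (edgeR adjusted p up to 0.063). Hemocyte markers differed in crq (−0.65), with 2 adjusted over the list alone (camera adjusted p = 0.0451, adjusted p = 0.562 with an estimated correlation), and the call ended without 1, 2, 5, 7, 8, 14 or 16 (up to 0.212), with RLE factors (0.0525) and with the 50 top genes out of scaling (0.0575). Without replicate 3, 2 hemocyte genes passed. Integrated stress genes differed in 4 of 12, 5 adjusted over the list alone, among them ImpL2 (−1.28) (camera adjusted p = 0.0407, adjusted p = 0.223 with an estimated correlation). That call ended without 1, 3, 7 or 16 (up to 0.0885), with total-count scaling (0.061) and with the 8 control libraries alone (0.0806).

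Between females and males labelled Myc RNAi, the yolk genes and dosage-compensation RNAs again differed, with Yp2 at 20.7 ± 15.3 against 0.106 ± 0.0737 CPM (log2 difference 7.45, SE 0.76, edgeR adjusted p = 2.95e-05) and roX1 at −9.25 (SE 0.47). Of 10 alpha-mannosidases and lysozymes 8 were higher in females (9 adjusted over the list alone), whereas 3 were higher in males among controls; LManV had 810 ± 226 and 202 ± 30.2 CPM (edgeR adjusted p = 8.43e-05). The interaction above tests that change. Bace (5.20, SE 0.42), LysP (3.77), LManIV (2.55), LManIII (2.37), Cyp4d1 (2.16), mwh (2.12), CG16700 (4.19) and CG8745 (3.98) were also higher in females. Higher in males were fs(1)Yb (−7.19), roX2 (−7.13), sev (−4.96), tyn (−3.45), AttD (−2.29) and, in a group whose replicate 16 held testis transcripts, Mst84B (−5.59), rha (−5.19), TTLL4B (−3.43), Argk2 (−1.99), CG32436 (−4.95) and CG32181 (−3.18). Without replicate 16 the values of these 6 genes were −1.94, −2.10, −0.63, −1.13, −1.50 and −1.63. No ribosome biogenesis gene differed between these groups (45 tested, camera adjusted p = 0.721), and Myc differed by 0.56 (edgeR adjusted p = 0.258).

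In all 518 genes differed between the sexes in the libraries labelled Myc RNAi, 265 higher in females and 253 higher in males, and 580 without replicate 16. The direction depended on the male libraries: 179 and 238 without 13, 225 and 365 without 14, and 157 and 255 without 15. The count was 294 without replicate 9, 315 without 10, 247 without 11 and 303 without 12, and 793 with DESeq2. Ends of calls after leaving out 1 library were found for LysP (9, 11, 12, 13 or 15; edgeR adjusted p up to 0.0654), mwh (11, 13 or 16; 0.103), Mst84B, TTLL4B and Argk2 (9, 10, 11, 12 or 16; 0.146, 0.325 and 0.109), rha and CG32181 (11; 0.0562 and 0.0513) and CG32436 (9 or 11; 0.0562). The call of Argk2 also ended with total-count scaling (edgeR adjusted p = 0.0552). Limma voom did not call Yp1, LManIV, mwh or the 6 genes just named for replicate 16 (adjusted p between 0.0519 and 0.254).

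Of 14 lists that camera called between the sexes labelled Myc RNAi, 3 held with an estimated correlation. Alpha-mannosidases and lysozymes were higher in females (camera adjusted p = 2.77e-15 preset, 0.0058 estimated). So were the tracheal genes Gasp (0.76) and serp (0.56), 2 of 9 members and 4 adjusted over the list alone (camera adjusted p = 0.00123 preset, 0.0454 estimated). The sex-determination list was called higher in males with a median of −0.10, with 5 members higher in females (3 without replicate 9, 10, 12, 13 or 16) and 4 in males, the same 5 and 4 adjusted over the list alone (camera adjusted p = 0.00469 preset, 0.0454 estimated), and this call ended with no filter on low counts (0.304). Enteroendocrine genes were higher in males for 4 of 21 (7 without replicate 14), 9 adjusted over the list alone, among them CCHa2 (−1.10) and AstC (−0.87) (camera adjusted p = 6.79e-05, adjusted p = 0.273 with an estimated correlation). V-ATPase subunits were higher in females for 4 of 23, 11 adjusted over the list alone, such as Vha100-4 (0.90) (camera adjusted p = 0.000119, adjusted p = 0.393 with an estimated correlation). Its member Vha68-3 had −4.09, and −0.05 without replicate 16 (edgeR adjusted p = 0.0472 and 0.964). That call also ended without 9, 10, 11 or 12, and 2 subunits were higher in females without 11 or 15. Antimicrobial and recognition genes were higher in males for 5 of 24 (2 without replicate 9 or 10 and 3 without 12 or 16), and adjusted over the list alone for 13 with 2 the other way (camera adjusted p = 0.000247, adjusted p = 0.495 with an estimated correlation). The neuronal gene para was higher in males (−2.77), 1 of 7 members and 1 adjusted over the list alone (camera adjusted p = 0.0158, adjusted p = 0.139 with an estimated correlation). That list call ended with no filter (0.0646) and with a filter of 1 CPM (0.139). The call of para ended without replicate 10 or 12 (edgeR adjusted p up to 0.0662), and that of serp without 9, 10, 11, 12, 13 or 15 (0.0998).

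The other lists called between these groups had few changed members. The visceral muscle genes Zasp52 (−1.37) and Act87E (−0.60) were higher in males, with 3 adjusted over the list alone (camera adjusted p = 0.0109, adjusted p = 0.393 with an estimated correlation), and the call ended without replicate 9 (0.0767). The damage signal vn was higher in males (−1.54), 1 member also adjusted over the list alone (camera adjusted p = 0.0383, adjusted p = 0.495 with an estimated correlation), and its list call ended without 9, 11, 12, 14 or 15 (up to 0.144) and with no filter (0.129); without 16, 3 members were higher in males. The region-restricted transcription factors lab (0.76), Antp (0.80) and bab2 (0.65) were higher in females, 3 also adjusted over the list alone (camera adjusted p = 0.0118, adjusted p = 0.547 with an estimated correlation), and the call ended without 16 (0.164). The calls of bab2 and Act87E ended without each replicate but 15 (edgeR adjusted p up to 0.112 and 0.129). No cell cycle gene passed, and 1 did without 13 (camera adjusted p = 0.00123, adjusted p = 0.547 with an estimated correlation). No glycolysis gene passed, and 1 did without 16 or adjusted over the list alone (camera adjusted p = 0.0168, adjusted p = 0.547 with an estimated correlation), with the call ending without 9 or 14 (up to 0.0863). Ribosomal proteins were called higher in females with RpS5b alone changed, higher in males (−2.73), and none adjusted over the list alone (camera adjusted p = 0.0158, adjusted p = 0.953 with an estimated correlation). The value of RpS5b was −0.71 without 16 (edgeR adjusted p = 0.364), and it did not pass without 9, 10, 11 or 12 either. Oxidative phosphorylation was called with no member changed (camera adjusted p = 0.0169, adjusted p = 0.953 with an estimated correlation). These 2 calls ended without 9, 11, 13, 14 or 15 (up to 0.22 and 0.237). Without 16 camera adjusted p was 2.56e-07 (median from 0.15 to 0.38) and 1.23e-06 (from 0.14 to 0.32). Mitochondrial ribosomal proteins were called without 16 only (median 0.20, camera adjusted p = 0.00131), as was the enterocyte list (0.0299), higher in males.

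How much of the sex difference in controls was present in the libraries labelled Myc RNAi was measured on held-out libraries. Genes chosen in pairs of control libraries, 79.8 on average over 36 choices, had a mean median log2 sex difference of 2.32 in the other control libraries and of 1.75 in the libraries labelled Myc RNAi, or 75.3% of it (jackknife SE 28.8 percentage points). The choices ranged widely, from 2 to 497 genes and from −3.14 to 8.60 in the held-out controls. On average 87.4% of the chosen genes kept their direction. Chosen and measured in all controls, 517 genes had medians of 1.04 and 0.38, or 36.9%, and with no filter on low counts the share was 125.3%. Across genes the sex differences of controls and of the libraries labelled Myc RNAi had a Pearson correlation of 0.377 and a Spearman correlation of 0.384. Of the genes higher in females 105 were called in both (13.3 from independent lists), among them Yp1, Yp2 and Bace, and of those higher in males 85 (13.3), among them roX1, sev and tyn. These comparisons share no library.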

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

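In this part the weighing of explanations, the splits and the search for outlying libraries were chosen after the results they bear on had been seen. The interaction test, the list tests, the other scalings and DESeq2 were set before. Effects that differed between the sexes by the interaction test, and libraries standing far from the other 3 of their group, are given here.

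The level of Myc in males labelled Myc RNAi is the first pattern, since it was 39.9 ± 13.6 CPM (SD, n = 4) against 25.5 ± 6.10 CPM in controls. Exchanged genotype labels are argued against by the white gene, since 0 of the 8 male libraries lay on the side of the other genotype. Scaling is argued against as well: the lowest male log2 fold change of Myc over 3 other scalings was 0.60. Myc was read in whole midguts, whereas mex1-GAL4 is an enterocyte driver, so its level in enterocytes alone was not measured. Reads of the RNAi hairpin counted as Myc remain a candidate explanation, because a common 32.3 CPM added to 29.9% of each control level would give the means of both sexes. With 2 unknowns for 2 values such a solution always exists, so this cannot be told apart from other explanations, a true difference between the sexes among them. These values include male Myc RNAi replicate 16, at 60.2 CPM, and the added CPM and kept share were not recomputed without it. Without that library the male log2 fold change was 0.38 (edgeR adjusted p = 0.248). The sexes' difference in effect was −1.24 (edgeR adjusted p = 0.155, DESeq2 adjusted p = 0.0438), and −0.97 without replicate 16 (edgeR adjusted p = 0.201). Total-count scaling called the male rise (1.09, edgeR adjusted p = 0.00606), and no protein level was analysed here.

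Testis transcripts in male Myc RNAi replicate 16 are the next. Its testis germline reads were 23981, against 12 to 34 in the other 3 libraries of the group, and 13845 genes had a count in it against 11041 to 11284. A response to the labelled genotype is argued against, since the 9 germline genes reached at most 1.36 CPM in the other 3 libraries and 517 CPM here, and depth is argued against, since the highest value among the 2 deeper libraries was 0.261 CPM. Testis tissue carried into the pool is consistent with 26 of 29 genes of a second testis list having at least 100 reads there, led by S-Lap1 with 15402 and S-Lap7 with 11306; a dissection that leaves the testis attached may be the source. In the same library the ribosomal protein score was 0.02 (others −0.79 to −0.68), the aminoacyl-tRNA synthetase score −0.11 (0.09 to 0.12), the neuron score 0.36 (0.27 to 0.29) and Yp1 0.233 CPM (0.039 to 0.0678).

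The fall of ribosomal proteins in females labelled Myc RNAi is the last weighed, with a difference in the mean log2 CPM of the list of −1.27 (SE 0.24, exact two-sided permutation p = 0.0286, the smallest this design can give). These genes have a short total exon length per gene (median 927 bases against 2086 for others). With a trend on that length removed within each library the difference was −1.30 (SE 0.17), which argues against length as the whole cause. Total-count scaling brought the list's median to −0.85, the nearest to 0 over 3 other scalings, and the list was still called. Without female control replicate 2, which has the highest score, the difference was −1.07 (SE 0.14). A lower share of enterocyte RNA could not be decided. Enterocyte markers were higher (score change 0.73, SE 0.08), while most members of the serine protease and starch digestion lists fell. Stem cell markers rose more than enteroendocrine ones by 1.26 (SE 0.26), where a loss of enterocytes alone would raise both alike. A change in stem cells could also give that gap, so it does not settle the question. Tracheal markers rose (0.60, SE 0.09) and visceral muscle markers changed little (0.09, SE 0.10). A change in stem cells and enteroblasts themselves (score change 1.22, SE 0.25) stays open beside the hypothesis that lower Myc activity reduces ribosomal protein transcripts, and the list call did not hold with an estimated correlation (adjusted p = 0.372).

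The split of libraries by genotype or sex was compared with other splits of the same libraries. For the effect in females 3362 genes were called and at most 2 in any other of the 35 splits; in males the values were 3671 and 23. For the sexes they were 959 and 63 in controls and 518 and 1 in the libraries labelled Myc RNAi. In each comparison the real split called the most genes of the 35. Chance alone gives that with a share of 1 in 35, the lowest this design allows. The other splits mix the groups, so a real difference between the groups lowers their calls. For the interaction 100 genes were called, and 82 in the highest of the other splits among 100 drawn. Those splits also exchange females and males, which breaks the sex difference itself. They do not test the interaction alone, and the part of chance in it stays open.

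By the interaction test the female minus the male log2 effect was 4.38 in LManIV, 3.45 in Bace, 3.16 in LManIII and 2.67 in LManV. It was 2.61 in LManVI, 3.87 in CG34316 and 2.95 in CG31091. A positive value does not mean a larger change in females, since the LMan genes and Bace fell in both sexes and more in males. The difference was negative in Zip42C.2 (−1.61), gol (−1.49), Gar1 (−1.43), Nop56 (−1.05), Fib (−1.04), CG6296 (−3.36) and CG31454 (−1.57). Of these, Nop56 fell in females and rose in males, gol rose more in males, and CG6296 fell in females alone. Lists that camera called at the preset correlation, given as medians of the female minus the male effect, were the Myc network (−0.20), ribosome biogenesis (−0.63), ribosomal proteins (−0.69), translation factors (−0.31) and mitochondrial ribosomal proteins (−0.34). Of these, ribosome biogenesis alone had members that passed over all genes and held with an estimated correlation. Without male Myc RNAi replicate 16 the medians were −0.33 for the Myc network, −0.46 for ribosomal proteins and −0.16 for mitochondrial ribosomal proteins, and these lists were still called. In the other direction were starch and sugar digestion (0.58), alpha-mannosidases and lysozymes (2.62), glycolysis (0.39), the copper and iron region (0.61), hemocyte markers (0.79), antimicrobial and recognition genes (0.60) and stress genes (0.67). No member of the antimicrobial or stress lists passed over all genes. The mannosidase and ribosome biogenesis lists alone held with an estimated correlation.

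Other libraries far from their group were male Myc RNAi replicate 13 with a lipid score of −0.24 (others −0.62 to −0.58), and female Myc RNAi replicate 9 with a visceral muscle score of −0.28 (0.01 to 0.05). Female Myc RNAi replicate 10 had a trachea score of 0.73 (0.43 to 0.47), and female control replicate 2 a mitochondrial ribosomal protein score of 0.59 (−0.03 to 0.04) and a Yp3 level of 98.6 CPM (48.4 to 51.7). Together 11 of 160 groups of 4 values held such a library, and chance gives about 1 in 20, or 8.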

How the results depend on the processing

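The alternatives for averaging the kept sex difference, the counts without male Myc RNAi replicate 16 as a doubted library and the gene families and length correction of the other parts were chosen after seeing the data; all other alternatives were set before. No paired analysis was possible because the libraries carry distinct numbers from 1 to 16. RLE factors, scaling without the 50 top genes, a filter of 1 CPM in 4 libraries, limma voom and the robust prior left every count of changed genes within 1.5 times its value above, and none of the first 3 moved the correlation or the kept share beyond its spread. Across settings no gene named by the rule reversed: leaving out a library of the comparison itself kept the call in 907 cases, ended it in 93 and gave a call to Myc in 4. Total-count scaling kept 106 calls, ended 5 and called Myc higher in males (1.09). DESeq2 kept 100, ended 11 through a missing adjusted p and called Myc in males (0.62) and in the interaction (−1.23), and voom kept 95 and ended 16. Of the 65 list calls, 61 kept under total-count scaling, 49 under fry and 6 with an estimated correlation. In the simulated data 26.9% of 2-fold interactions were recovered; depth was not varied.

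Under total-count scaling the interaction held 57 genes, and the medians of fatty acid oxidation in females (0.05) and glycolysis in males (0.10) reversed, since the median of all genes moved by more. With no filter the counts were 293 for the sexes labelled Myc RNAi and 59 for the interaction, the correlation of the effects was 0.217 and the kept share 125.3%; more low-count genes enter by construction. At an adjusted p under 0.01 the counts were 355 for the sexes in controls, 183 for those labelled Myc RNAi and 24 for the interaction. Against a 1.5-fold change they were 1313, 1658, 116, 77 and 13 in the order females, males, sexes in controls, sexes labelled Myc RNAi, interaction. With the 8 control libraries alone the sexes differed in 538 genes. DESeq2 gave 793 for the sexes labelled Myc RNAi and 243 for the interaction; the cause was not tested. In the same order the lists called were 0, 1, 0, 3 and 2 with an estimated correlation, which allows for members that vary together, against 11, 12, 16, 14 and 12 with the preset one. Fry, which does not compare a list with other genes, called 20 in females, 22 in males and 7 each for the sexes labelled Myc RNAi and the interaction. The kept share was 36.9% when genes were chosen and measured in all controls, and 68.7%, 69.5% and 65.6% for the mean of the ratios, for choices with at least 10 genes and for both.

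Leaving out each library in turn gave 2902 to 3725 genes in females, 3183 to 3861 in males, 574 to 1292 for the sexes in controls, 247 to 590 for those labelled Myc RNAi and 36 to 131 for the interaction; the cause was not tested. The lists called ranged from 11 to 13, 11 to 13, 13 to 19, 9 to 16 and 11 to 16, with 9 for the sexes labelled Myc RNAi without replicate 9. The correlation ranged from 0.545 to 0.758 and the kept share from 59.8% to 91.5%.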

Other observations

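The families of this part and the choice of its genes came after the data were seen. The family tests and the X chromosome test were not set beforehand, whereas the edgeR gene and interaction tests were. Some of these genes were also named above by the rule or belong to the fixed lists. Members of the detoxification families moved both ways. Of 68 cytochrome P450 genes 27 fell and 12 rose in females, with a median log2 change of −0.38 that total-count scaling turned to 0.06 (camera adjusted p = 0.00464, adjusted p = 0.113 with an estimated correlation). In males 31 fell and 12 rose, with a median of −0.69 (adjusted p = 0.0129 with an estimated correlation, and 0.137 with total-count scaling). With total-count scaling 20 P450 genes fell and 18 rose in females, and 24 fell and 15 rose in males. Cyp6g1, which metabolises insecticides, fell by 2.65 in females and 3.87 in males, and Cyp4ac1 fell by 1.75 and 2.73, while Cyp12e1 rose (3.60 and 3.67). Of 28 UDP-glycosyltransferase genes 14 fell and 4 rose in females and 15 fell and 3 rose in males, with medians of −0.46 and −0.68 (adjusted p = 0.113 and 0.0129 with an estimated correlation). With total-count scaling 8 Ugt genes rose and 6 fell in females, and 8 rose and 13 fell in males. The male Ugt call with an estimated correlation ended there (median −0.20, adjusted p = 0.137). Camera at the preset correlation still called the male Ugt and P450 lists with that scaling (adjusted p = 3.15e-06 and 1.42e-07). Ugt37B1 (−3.53 and −4.06) and Ugt35C1 (−2.20 and −3.79) were among the Ugt genes that fell, and Ugt301D1 rose (2.72 and 2.04). In both families the median change was lower in males than in females. In the interaction test 3 P450 and 2 Ugt genes passed, each with a positive female-minus-male difference (list adjusted p = 0.0133 and 0.0081 with an estimated correlation). With total-count scaling 0 and 1 passed and both list calls with an estimated correlation ended (adjusted p = 0.104). The medians there were 0.244 and 0.371, against 0.309 and 0.415 with TMM, and camera at the preset correlation still called both (adjusted p = 3.13e-07 each).

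A list of genes with Cht (chitinase) and Idgf symbols was also examined. In females 5 of 15 genes rose and none fell, namely Cht12 (3.36), Cht4 (2.85), Cht9 (2.58), Cht2 (2.15) and Cht10 (edgeR adjusted p = 0.0301). In males 6 rose, these 5 and Idgf3 (0.98). Camera adjusted p was 0.00557 and 0.026, and neither call held with an estimated correlation (adjusted p = 0.113 and 0.233). The male call ended with total-count scaling (camera adjusted p = 0.123), where 9 genes rose, 0 fell and the median went from 0.58 to 1.1. The metal-binding metallothioneins MtnC (−1.58), MtnD (−1.70) and MtnE (−1.95) fell in males (list adjusted p = 0.271 with an estimated correlation).

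Genes on the X chromosome were counted among sex-biased genes. In controls 27% of the genes higher in females and 20% of those higher in males were X-linked, against 16.6% of all tested genes with a position (Fisher's exact test over genes, adjusted p = 2.59e-08 and 0.0457). In the libraries labelled Myc RNAi the shares were 29.8% and 26.6% (adjusted p = 1.11e-07 and 6.41e-05); genes are not independent replicates.

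A few genes had many more reads in the libraries labelled Myc RNAi than in controls. Hsp70Bb had 5 and 4 reads over the female and male controls against 10759 and 9442, while its near-identical copies changed little or less: Hsp70Ba had 16 and 39 against 123 and 170, Hsp70Bbb 12 and 13 against 18 and 10, and Hsp70Bc 13 and 13 against 11 and 24. The pair-rule gene ftz had no read in controls against 626 and 565, and HmgD had 1690 and 2635 against 45188 and 46003. The 9 testis germline genes held 12 to 34 reads in the 7 libraries labelled Myc RNAi other than replicate 16 and 0 to 5 in the controls. No explanation was tested for these values.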
